A study of Mus musculus with 12 samples.

How the data were processed

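RNA was measured in G1E-ER4 cells, a mouse erythroid progenitor line that lacks GATA1 and carries an estradiol-activated form of it. Per the labels, cells received a control siRNA (siControl) or an siRNA against ZIP10, the zinc importer encoded by Slc39a10 (siZIP10), in 2 transfections 24 h apart. Differentiation was induced with 100 nM β-estradiol at the second transfection. Zinc was lowered in a part of the cultures with 25 µM DTPA, a chelator that binds zinc outside the cell, from the start of differentiation, and all cells were harvested 24 h later. The 4 groups were siControl, siControl plus DTPA, siZIP10 and siZIP10 plus DTPA, with 3 biological replicates each. Libraries were made from poly(A) RNA with a stranded kit.

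The deposited values of all 12 libraries are TPM, transcripts of a gene among 1e+06, so that each library sums to 1e+06. Per the submitters' processing notes, Trimmomatic 0.33, FastQC, HISAT2 2.1.0, featureCounts, edgeR and the mm10 build were used; their order and settings, the annotation and the strand setting are not given in the sources used here. Each library lists 55487 genes with 55367 distinct names, of which 114 occur more than once and 53365 match GENCODE mouse release 21. Gene positions, exon lengths and biotypes were taken from that release. Because the strand setting is unknown, values of genes that overlap others on either strand are uncertain, and so is the division of reads among near-identical globin copies.

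TPM values carry no read counts. Multiplied by exon length, they fell on whole multiples of a unit specific to each library, and that unit was used to recover reads. Between 98.9% and 99.1% of the values of up to 20 reads were whole numbers within 0.1 read. The recovered depth was 19.63 to 24.69 M reads (1 M is 1e+06) per library.

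The values deposited for siControl plus DTPA replicate 3 were identical to those of siZIP10 replicate 1 for all 55487 genes, under a column heading that names the siZIP10 library. Among genes above 0 in either library, any other pair of libraries shared at most 0.012% of its values. The design fixed before the data were examined assumed 12 libraries; this library was left out of every comparison, so that 11 libraries were used and siControl plus DTPA had n = 2.

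Genes with a mean of at least 1 TPM over the 11 libraries were tested (11379 genes). Values were analysed as log2(TPM + 1), which understates changes of genes with low TPM. The moderated test of limma 3.58.1 with a trend on mean expression was run in R 4.3.3 on a model with 4 group means (7 residual degrees of freedom, prior degrees of freedom 3.21). Each p was two-sided and adjusted over genes by the Benjamini-Hochberg method with a threshold of 0.05, separately in 6 comparisons. Low zinc is siControl plus DTPA against siControl, low ZIP10 is siZIP10 against siControl, and the double treatment is siZIP10 plus DTPA against siControl. The other 3 are DTPA within the knockdown, the knockdown within DTPA, and the interaction, which is the DTPA effect with the knockdown minus the DTPA effect without it. Changes are log2 differences of group means with the standard error (SE) of the model; levels are mean TPM ± standard deviation (SD). Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

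The 26 gene lists (465 genes) fixed before the data were examined were metallothioneins with Slc30a1 (targets of the zinc sensor MTF1), ZIP zinc importers, ZnT zinc exporters, heme synthesis, globins, iron uptake and storage, red cell membrane and cytoskeleton, erythroid transcription factors and regulators, progenitor genes repressed in erythroid maturation, mitosis, DNA replication, p53 targets, amino acid response (ATF4 targets), unfolded protein response, oxidative stress (NRF2 targets), heat shock, interferon response, autophagy and mitophagy, glycolysis, ribosome biogenesis, cholesterol synthesis, cell death regulators, and markers of megakaryocytes, mast cells and basophils, myeloid cells and lymphoid cells. Slc30a1 is in the MTF1 and ZnT lists and Gata2 is in the progenitor and mast cell lists. Hmox1 is in the iron and NRF2 lists and Slc7a11 in the ATF4 and NRF2 lists. Such shared genes are counted in each of their lists among the 465. The globin list also holds Ahsp, which is not a globin gene. Below, red cell membrane genes are members of the red cell membrane and cytoskeleton list. That list also holds the carbonic anhydrase genes Car1 and Car2. The 23 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, again with an estimated correlation, and with fry. fry tests whether a list's genes move on balance in 1 direction and does not compare the list with other genes. Counts of called list members are those of the main fit, and members near the threshold can lose their call in other fits.

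The rule for named genes, also fixed before the data were examined, took Slc39a10, Mt1, Mt2 and Slc30a1 in every comparison. It added the 8 largest rises and the 8 largest falls among called genes whose groups did not overlap and whose mean was at least 5 TPM in a group, and for the interaction the 5 largest each way with no rule on overlap. Predicted genes without a symbol were passed over. Up to 4 members of each list with the smallest adjusted p were added as examples. Genes named outside this rule are said to have been chosen after their values were seen.

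The relation between the zinc and ZIP10 effects was described by Pearson's r and Spearman's rho across genes for the average effects of the design and for the contrasts against the shared control, beside values from 100 simulations with no effect. The overlap of calls was set beside the number that independence would give and the number in the simulations. The test was also run on simulated data in which 200 of 11379 genes were changed, in 20 draws. For a log2 change of 0.3, 0.5 and 1 it recovered 46.1%, 69.8% and 90.5% of the changed genes for low zinc, 52.7%, 75% and 90.8% for low ZIP10, and 53.1%, 74% and 90.7% for the double treatment. False calls made up 4.98%, 4.43% and 4.29% of the calls. The simulated data had independent normal errors and far fewer changed genes than were called in the real data. These shares therefore need not hold for the real libraries.

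Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-of-ratios scaling, quantile normalization, a replicate block, no trend, only the groups compared, and leaving out each of the 11 libraries in turn. Added after the data were seen were a fit with the duplicated library as labelled, limma voom on the recovered reads, and a rescaling of each library to its nuclear protein-coding genes.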

Results

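Gene expression was measured by RNA sequencing in differentiating G1E-ER4 mouse erythroid cells. They received the chelator DTPA to lower zinc, an siRNA against Slc39a10 to lower ZIP10, both treatments, or neither. With both, the Slc39a10 transcript was 24.2% of its level with DTPA alone but 194.5% of control. ZIP10 protein and zinc were not measured here, and no group had zinc added back. Low zinc therefore names the DTPA treatment below, and effects of DTPA through other metals were not tested. There were 3 libraries each of siControl, siZIP10 and siZIP10 plus DTPA. The siControl plus DTPA group had 2, because the values given for its replicate 3 were those of siZIP10 replicate 1. The recovered depth was 19.63 to 24.69 M reads (1 M is 1e+06) per library, and 15225 to 16147 genes were above 0. Correlations of log2 values were 0.988 to 0.991 between libraries of a group and 0.939 to 0.986 between groups. The double-treated libraries differed in make-up from the others. Mitochondrial rRNA made up 1.43% to 1.45% of their TPM and 0.26% to 0.42% in the other groups, ribosomal protein genes 10.47% to 10.81% against 7.86% to 9.27%, and nuclear protein-coding genes 77.33% to 79.64% against 82.64% to 84.08%.

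Slc39a10, the gene targeted by the siRNA (ENSMUSG00000025986.6, mm10 chromosome 1, 46807544 to 46892852, minus strand), was expressed at a low level in control cells. It stood at 2.78, 2.31 and 2.78 TPM in siControl replicates 1 to 3 (129, 98 and 105 reads). In siZIP10 it stood at 0.539, 0.507 and 0.837 TPM (21, 21 and 36 reads). It was far higher under DTPA, with 22 and 20.3 TPM (986 and 942 reads) in the pair of siControl plus DTPA libraries. With both treatments it stood at 5.36, 4.93 and 5.02 TPM (242, 250 and 212 reads). Slc39a10 thus rose 8.05-fold in TPM with low zinc in control cells (log2 change 2.61, SE 0.12, adjusted p = 3.73e-07) and 8.14-fold in knockdown cells (1.91, SE 0.1, adjusted p = 6.32e-08). The knockdown left 23.9% of the transcript at normal zinc (−1.16, adjusted p = 2.37e-05) and 24.2% at low zinc (−1.86, adjusted p = 3.25e-07). With a pseudocount of 0.1 and with voom the change with the knockdown at normal zinc was larger (−1.93 and −2.05), as was that with low zinc in knockdown cells (2.87 and 3.1). Doubly treated cells held 194.5% of the control level (0.75, adjusted p = 7.74e-05). The interaction of −0.70 (adjusted p = 0.00604) depended on the pseudocount at this low level: it was −0.1 with a pseudocount of 0.1 (adjusted p = 0.81) and 0.05 with voom (adjusted p = 0.891). With the duplicated library as labelled, the change with low zinc was 1.33 and no Slc39a10 call remained (adjusted p = 0.0542 to 0.723).

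Metallothionein transcripts were low in every DTPA library and high in the others. Mt1 (ENSMUSG00000031765.8, chromosome 8, 94179082 to 94180327) and Mt2 (ENSMUSG00000031762.7, chromosome 8, 94172664 to 94173568) encode metallothioneins, which bind zinc and are induced by it. Mt1 fell from a mean of 1706.8 TPM in siControl (1627.4 to 1804.5, n = 3) to 172.8 ± 3.81 in siControl plus DTPA (SD, n = 2), 10.1% of control (log2 change −3.30, SE 0.06, adjusted p = 1.9e-10). Mt2 fell from 2038.9 ± 72.4 to 17.1 ± 2.98 TPM, 0.837% of control (−6.83, SE 0.12, adjusted p = 1.9e-10). With the knockdown alone Mt1 stood at 1996.8 ± 135.6 TPM, a rise of 0.23 (SE 0.05, adjusted p = 0.00875) that was not called under quantile normalization (0.18). Mt2 then stood at 2413.0 ± 72.8 TPM (0.24, adjusted p = 0.122). That change passed the threshold with only the groups compared (0.24, adjusted p = 0.00299), with voom (0.26, adjusted p = 2.52e-07) and without siZIP10 plus DTPA replicate 2 (0.24, adjusted p = 0.0464). With both treatments Mt1 was 269.1 ± 10.7 and Mt2 22.1 ± 3.81 TPM, below control (−2.66 and −6.48) and, for Mt1, above DTPA alone (0.64, adjusted p = 6.55e-06). For Mt2 the rise over DTPA alone was 0.35 (adjusted p = 0.033). It was lost without siControl plus DTPA replicate 2 (0.18, adjusted p = 0.313), siZIP10 plus DTPA replicate 1 (0.37, adjusted p = 0.0551) or siZIP10 plus DTPA replicate 2 (0.22, adjusted p = 0.0855), with no filter (adjusted p = 0.0835), without the trend (adjusted p = 0.0541), with only the groups compared (adjusted p = 0.109) and under voom (0.43, adjusted p = 0.106).

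Slc30a1 (ENSMUSG00000037434.7, chromosome 1, 191906767 to 191913247), which encodes the zinc exporter ZnT1 and is a further MTF1 target, did not fall with DTPA as the metallothioneins did. It stood at 82.5 ± 2.94 TPM in siControl and 90.1 ± 3.45 with DTPA (log2 change 0.13, adjusted p = 0.068). This change passed the threshold under 5 alternative scalings or fits (0.14 to 0.18) and without siControl replicate 1 (0.15, adjusted p = 0.042). The knockdown raised Slc30a1 to 114.6 ± 4.77 TPM (0.47, SE 0.04, adjusted p = 2.1e-05). With both treatments it rose to 241.9 ± 8.91 TPM, 293.2% of control (1.54, adjusted p = 2.01e-10), more than the sum of the separate changes (interaction 0.95, adjusted p = 1.92e-06).

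**Figure D1:**
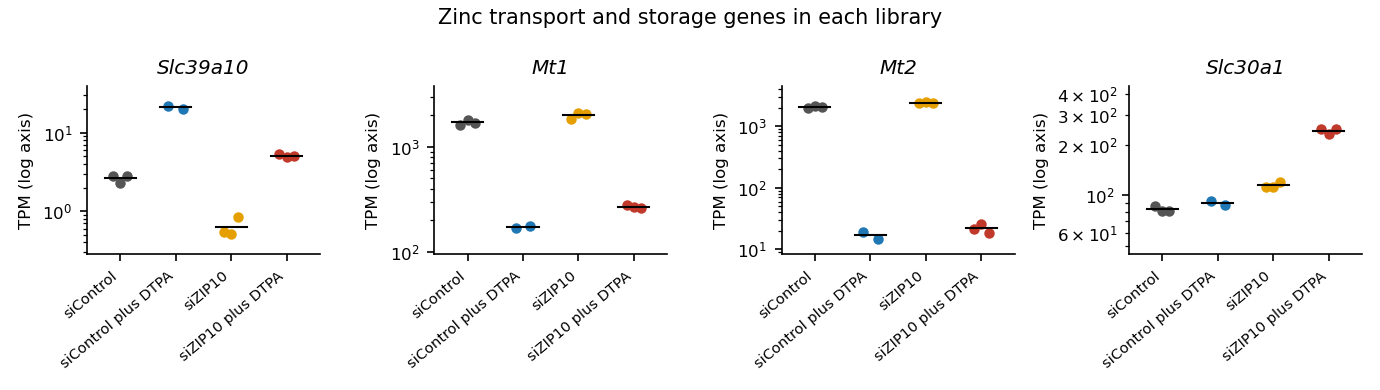
TPM (log axis) of Slc39a10, Mt1, Mt2 and Slc30a1 in each library of the 4 groups, with a bar at the group mean. Slc39a10 averaged 2.62, 21.1, 0.627 and 5.1 TPM, and Slc30a1 82.5, 90.1, 114.6 and 241.9 TPM, in siControl, siControl plus DTPA, siZIP10 and siZIP10 plus DTPA.

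The first comparison asked what DTPA alone did, which is called low zinc here. Embryonic β-like globin transcripts were among the largest rises. Hbb-bh1 (ENSMUSG00000052217.6, chromosome 7, 103841637 to 103843164) went from 142.4 ± 2.88 to 1138.5 ± 6.81 TPM (log2 change 2.99, SE 0.04, adjusted p = 2.99e-11), and Hbb-y from 23.0 ± 5.38 to 104.1 ± 4.96 TPM (2.16, adjusted p = 4.59e-06). Alpk3, which encodes a muscle kinase, rose from 3.01 to 9.8 TPM (1.43). Among the largest falls were Slc52a3, a riboflavin transporter (15.9 to 3.79 TPM, −1.81), Rhd, the Rh blood group antigen (15.7 to 4.35 TPM, −1.64), the cell cycle repressor E2f8 (16.4 to 5.19 TPM, −1.48) and Uhrf1, which helps to maintain DNA methylation (29.5 to 10.4 TPM, −1.41).

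Genes of cell division fell with low zinc. All 21 mitosis genes fell, with a median of −1.08 (camera adjusted p = 6.88e-18, and adjusted p = 0.00387 with an estimated correlation; 21 also passed when adjusted over the list alone). Among them were the proliferation marker Mki67 (174.6 to 82.1 TPM, −1.08), cyclin A (Ccna2, 205.2 to 105.6 TPM, −0.95) and the spindle gene Nusap1 (−1.19). Of 25 DNA replication genes, 22 fell and 3 did not pass (24 passed when adjusted over the list alone), with a median of −0.58 (adjusted p = 1.96e-13, and adjusted p = 0.0163 with an estimated correlation). Examples were the helicase gene Mcm6 (43.7 to 21.9 TPM, −0.97), Mcm3 (−0.97) and Rrm2 of ribonucleotide reductase (−1.27).

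All 19 genes of cholesterol synthesis fell by a small amount (median −0.32, 19 when adjusted over the list alone, camera adjusted p = 1.25e-11), for example Hmgcs1 (267.4 to 192.1 TPM, −0.48) and Sqle (−0.50). For that list the adjusted p = 0.0679 with an estimated correlation. Of 19 p53 targets 12 rose and 1 fell (13 when adjusted over the list alone), with a median of 0.15 (adjusted p = 2.15e-06, but adjusted p = 0.0605 with an estimated correlation). Bbc3, a promoter of cell death, rose from 113.7 to 158.4 TPM (0.48), and Zmat3 (0.48) and Ccng1 (0.27) rose as well. Of 9 tested members of the globin list 4 rose and 5 did not pass (4 when adjusted over the list alone), with a median of 0.34 and a mean of 0.84 (adjusted p = 0.000148, but adjusted p = 0.0653 with an estimated correlation). Hba-x, the embryonic α-like globin, rose by 1.19. Adult Hbb-bs went from 21530.5 to 29325.9 TPM (0.45), a call lost under quantile normalization (0.23) and with no filter (adjusted p = 0.0819).

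Among stress lists, 12 of 21 amino acid response genes fell (12 when adjusted over the list alone, median −0.18, adjusted p = 0.000352, but adjusted p = 0.126 with an estimated correlation), for example the serine pathway genes Shmt2 (−0.60) and Psat1 (−0.41). Of 18 NRF2 targets 11 fell (13 when adjusted over the list alone, median −0.13, adjusted p = 0.000917, but adjusted p = 0.079 with an estimated correlation), among them the quinone reductase Nqo1 (75.9 to 39.6 TPM, −0.92) and Txnrd1 (−0.48). Of 14 heat shock genes 8 fell (9 when adjusted over the list alone, median −0.15, adjusted p = 0.00322, but adjusted p = 0.373 with an estimated correlation), such as the co-chaperone Stip1 (−0.48). Of 18 autophagy genes 8 rose (9 when adjusted over the list alone, median 0.09, adjusted p = 0.00315, but adjusted p = 0.248 with an estimated correlation), such as the receptor gene Sqstm1 (0.29). Of 24 ribosome biogenesis genes 9 fell (9 when adjusted over the list alone, median −0.15, adjusted p = 0.0205, but adjusted p = 0.373 with an estimated correlation). That call was also lost after rescaling to nuclear protein-coding genes (adjusted p = 0.0634). Of 4 megakaryocyte markers 2 rose (3 when adjusted over the list alone, median 0.54, adjusted p = 0.00322, but adjusted p = 0.0653 with an estimated correlation), namely the platelet receptor genes Itgb3 (0.75) and Gp1ba (0.33). The metallothionein list, with 2 of 3 members lower (3 when adjusted over the list alone), had a median of −3.30 (adjusted p = 0.00651, but adjusted p = 0.0679 with an estimated correlation).

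The heme, red cell and erythroid regulator lists went both ways and were not called. Of 18 heme synthesis genes 4 rose and 4 fell (8 when adjusted over the list alone, adjusted p = 0.749): Alad, a zinc-dependent enzyme, fell from 514.0 to 315.1 TPM (−0.70), whereas Uros (0.46) and Alas2 (2036.5 to 2472.3 TPM, 0.28) rose. Of 21 red cell membrane genes 4 rose and 8 fell (13 when adjusted over the list alone, adjusted p = 0.166), and Slc4a1 (ENSMUSG00000006574.15, chromosome 11, 102348824 to 102366203), the band 3 anion exchanger, fell from 445.0 ± 5.76 to 233.8 ± 10.8 TPM (−0.93). Of 18 erythroid regulators 6 rose and 6 fell (12 when adjusted over the list alone, adjusted p = 0.384), with Gfi1b up (435.0 to 649.0 TPM, 0.58) and Gata1 down (2067.0 to 1457.5 TPM, −0.50). The line lacks GATA1 and carries an introduced form of it. In every comparison, Gata1 reads may therefore come from that form, which was not told apart here. Of 13 progenitor genes 4 rose and 2 fell (8 when adjusted over the list alone, adjusted p = 0.07), including the receptor gene Kit (0.48). In the iron list 3 of 16 rose and 2 fell (6 when adjusted over the list alone, adjusted p = 0.619). The 8 tested ZIP importers of the list, which leaves out Slc39a10, held no call in limma, none at an unadjusted p of 0.05, none adjusted over the list alone and none with voom (adjusted p = 0.709 for the list). Of 6 ZnT exporters 1 rose, Slc30a10 (96.4 to 126.4 TPM, 0.39), and 1 fell, Slc30a9 (4 when adjusted over the list alone, adjusted p = 0.439). The call of Slc30a9 (−0.19) was lost without siControl plus DTPA replicate 2 (−0.18, adjusted p = 0.0698).

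The unfolded protein response (1 of 17 rose and 6 fell, 7 when adjusted over the list alone, adjusted p = 0.0648), glycolysis (5 of 18 rose and 8 fell, 13 when adjusted over the list alone, adjusted p = 0.619), interferon (1 of 10 fell, 1 when adjusted over the list alone, adjusted p = 0.709) and cell death lists (1 of 15 rose and 2 fell, 2 when adjusted over the list alone, adjusted p = 0.997) were not called. The counts for cell death were not stable: the 1 rise, Apaf1 (0.12), lost its call in 10 alternatives, of which 6 left out a library, and Mcl1 (−0.10) lost its call in 7, among them those without either siControl plus DTPA library. The unfolded protein response was called with a replicate block (adjusted p = 0.0281) and with no filter (adjusted p = 0.00499), and the red cell list with no filter (adjusted p = 0.042). The median, the mean and the test differed in sign for the ZIP, heme, iron, erythroid regulator and cell death lists. Of the other lineages, Hdc of the mast cell list rose (0.63), a call lost with only the groups compared (adjusted p = 0.0523), while Gata2 stood at −0.01, and the myeloid Cd68 (0.11) and the lymphoid Cd79a (0.07) were not called. In all, limma called 3272 of 11379 genes, 1136 higher and 2136 lower, and 31 of the higher and 78 of the lower ones changed at least 2-fold. The share of higher calls, 34.7%, depended on scaling: it was 47.7% with median-of-ratios scaling, 51.1% after quantile normalization and 47.2% with voom. It was 36.5% after rescaling to nuclear protein-coding genes. Of the 12 lists called, 2 were kept with an estimated correlation, mitosis and DNA replication.

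The second comparison asked what the siRNA against Slc39a10 alone did, which is called low ZIP10 here. No group had a different siRNA against Slc39a10 or ZIP10 restored. Effects of the siRNA on other targets therefore cannot be told apart from those of low ZIP10. Mitotic genes made up most of the largest falls. Cyclin B (Ccnb2) fell from 96.0 to 30.2 TPM (log2 change −1.64), the survivin gene Birc5 from 66.1 to 21.3 TPM (−1.59), the mitotic kinase gene Plk1 from 57.1 to 18.4 TPM (−1.58), and the kinesin gene Kif20a by 1.56. Rises were smaller. Ypel4 went from 38.7 to 79.0 TPM (1.01), Tspo2, which encodes an erythroid membrane protein that binds porphyrins, from 10.3 to 21.3 TPM (0.98), the actin regulator Fhdc1 from 23.0 to 45.8 TPM (0.97), and Tmem140 from 26.2 to 47.7 TPM (0.84).

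All 21 mitosis genes fell (21 when adjusted over the list alone), with a median of −1.32 (camera adjusted p = 6.78e-23, and adjusted p = 0.00175 with an estimated correlation), including Mki67 (−1.18), Ccna2 (−1.13) and Top2a (−1.28). Of 25 DNA replication genes 23 fell (25 when adjusted over the list alone), with a median of −0.81 (adjusted p = 1.7e-18, and adjusted p = 0.00619 with an estimated correlation), such as the licensing factor Cdc6 (−1.10) and Rrm2 (−1.29). Of 19 p53 targets 12 rose and 2 fell (16 when adjusted over the list alone, median 0.20, adjusted p = 1.97e-05, but adjusted p = 0.0874 with an estimated correlation), with Bbc3 (0.50) and Bax (0.24) among them. Of 18 autophagy genes 10 rose (10 when adjusted over the list alone, median 0.10, adjusted p = 0.000975, but adjusted p = 0.273 with an estimated correlation): Sqstm1 went from 662.1 to 909.8 TPM (0.46) and the mitophagy receptor Bnip3 rose by 0.41. Of 17 unfolded protein response genes 10 fell and 2 rose (12 when adjusted over the list alone, median −0.16, adjusted p = 0.00349, but adjusted p = 0.355 with an estimated correlation), with the chaperone genes Hspa5 (−0.36) and Calr (−0.38) among the falls. Of 10 interferon genes 5 rose (5 when adjusted over the list alone, median 0.32, adjusted p = 0.0108, but adjusted p = 0.273 with an estimated correlation), for example Bst2 (0.67). That call was lost with a filter of 5 TPM (adjusted p = 0.132).

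Ribosome biogenesis, with 9 of 24 genes lower and 3 higher (13 when adjusted over the list alone, median −0.12), passed at an adjusted p = 0.0238, but had an adjusted p = 0.514 with an estimated correlation. It was lost with a filter of 5 TPM (adjusted p = 0.0836) and after rescaling to nuclear protein-coding genes (adjusted p = 0.0529), and its examples were Dkc1 (−0.60) and Nolc1 (−0.39). The metallothionein list, with 2 of 3 members higher (3 when adjusted over the list alone, median 0.24, adjusted p = 0.0213, but adjusted p = 0.164 with an estimated correlation), was lost under quantile normalization (adjusted p = 0.0791).

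The red cell, heme, erythroid regulator and globin lists were not called. In red cell membrane genes 2 of 21 rose and 9 fell (14 when adjusted over the list alone, adjusted p = 0.0506), with Slc4a1 at 304.3 TPM (−0.55) and the potassium channel gene Kcnn4 (−0.84). In heme synthesis 4 of 18 rose and 8 fell (13 when adjusted over the list alone, adjusted p = 0.241): Alad fell to 347.1 TPM (−0.57). Among erythroid regulators 2 of 18 rose and 3 fell (5 when adjusted over the list alone, adjusted p = 0.593), with Gata1 at 1552.1 TPM (−0.41) and Klf1 (−0.22). Of 9 tested members of the globin list 2 rose, Hbb-bs (0.29) and Hbb-y (0.39), and 1 fell (3 when adjusted over the list alone, adjusted p = 0.929). Neither rise was stable. Hbb-bs lost its call with no filter (adjusted p = 0.216) and under quantile normalization (0.09). Hbb-y lost it with no filter (adjusted p = 0.116), without the trend (0.0724), with only the groups compared (0.108) and in 9 of the 11 fits that left out a library (0.21 without siControl replicate 3). Hba-x fell by 0.87, opposite to its rise with low zinc, Hba-a1 stood at −0.09 (adjusted p = 0.228) and Hbb-bh1, chosen after its values were seen, at −0.04 (adjusted p = 0.475). Of 8 importers Slc39a6 (8.53 to 12.8 TPM, 0.53) and Slc39a8 (0.17) rose (2 when adjusted over the list alone, adjusted p = 0.28). The heme-degrading enzyme gene Hmox1 rose from 157.1 to 237.9 TPM (0.59).

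Not called were the exporters (2 of 6 rose, 2 when adjusted over the list alone, adjusted p = 0.321), iron (6 of 16 rose and 4 fell, 10 when adjusted over the list alone, adjusted p = 0.321), progenitor genes (4 of 13 rose and 2 fell, 7 when adjusted over the list alone, adjusted p = 0.269), the amino acid response (3 of 21 rose and 3 fell, 6 when adjusted over the list alone, adjusted p = 0.73) and NRF2 targets (2 of 18 rose and 7 fell, 10 when adjusted over the list alone, adjusted p = 0.321). Heat shock (3 of 14 rose and 7 fell, 10 when adjusted over the list alone, adjusted p = 0.176), glycolysis (4 of 18 rose and 5 fell, 12 when adjusted over the list alone, adjusted p = 0.338), cholesterol synthesis (1 of 19 rose and 7 fell, 8 when adjusted over the list alone, adjusted p = 0.0621), cell death (3 of 15 rose, 3 when adjusted over the list alone, adjusted p = 0.269) and megakaryocyte lists (1 of 4 rose, 2 when adjusted over the list alone, adjusted p = 0.409) were not called either. The rise of the cell death gene Mcl1 (0.08) was lost in 7 alternatives. With no filter the red cell list (adjusted p = 0.00879) and the cholesterol list (adjusted p = 0.00822) were called. The median, the mean and the test differed in sign for the globin, erythroid regulator, amino acid response, glycolysis and megakaryocyte lists. Of the mast cell list Gata2 fell by 0.26 and Hdc rose by 0.43. The call of Hdc was lost with only the groups compared (adjusted p = 0.0895) and without siControl replicate 2 (0.33, adjusted p = 0.05) or siZIP10 replicate 1 (0.36, adjusted p = 0.0555). Cd68 (0.36) and Cd79a (0.16) were not called. In all, limma called 3480 genes, 1493 higher and 1987 lower, of which 11 and 113 changed at least 2-fold. The share of higher calls was 42.9%, 48.4% with median-of-ratios scaling, 54.3% after quantile normalization, 48.6% with voom and 43.2% after rescaling to nuclear protein-coding genes. Mitosis and DNA replication were the 2 of 8 called lists that were kept with an estimated correlation.

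**Figure D2:**
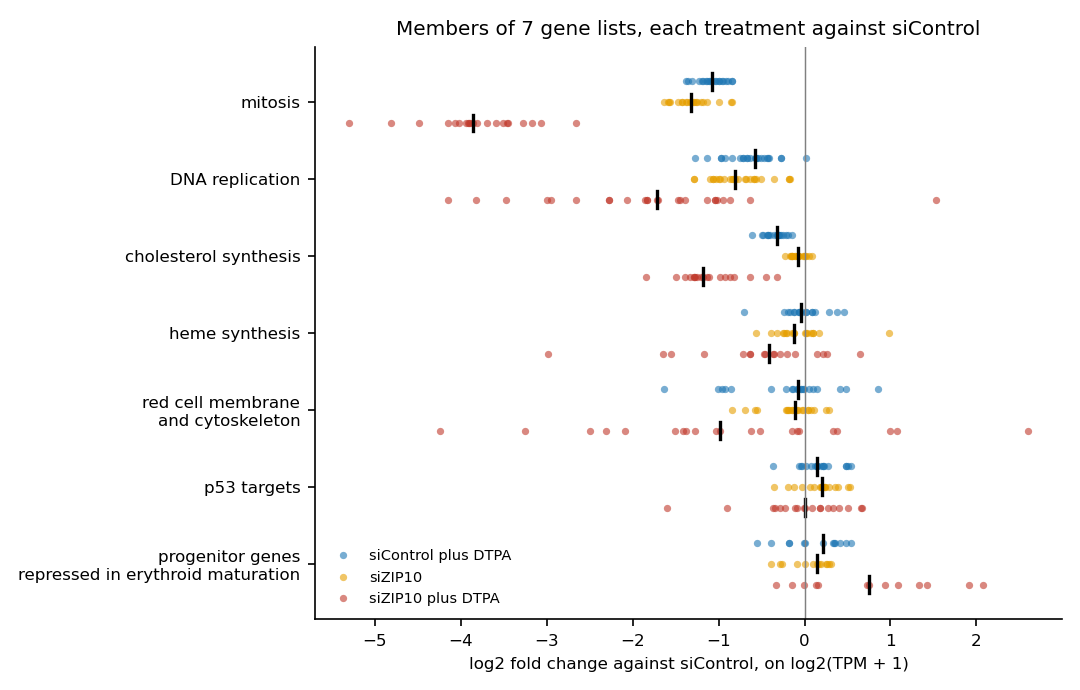
Log2 change against siControl of the tested members of 7 fixed lists (dots) with their median (black bar), under low zinc, low ZIP10 and the double treatment. The mitosis median was −1.08, −1.32 and −3.86, and that of red cell membrane genes −0.08, −0.11 and −0.98.

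The third comparison asked what both treatments did together. Doubly treated cells held far less of the transcripts of cell division and of Slc4a1, and more of the embryonic globin transcripts Hbb-bh1 and Hbb-y, while embryonic Hba-x was not called (0.23, adjusted p = 0.161). Nusap1 fell from 117.0 to 1.99 TPM (log2 change −5.30), the motility receptor Hmmr from 61.5 to 0.644 TPM (−5.25) and the mitotic ubiquitin enzyme Ube2c from 198.6 to 4.74 TPM (−5.12). Slc4a1 fell from 445.0 ± 5.76 to 22.5 ± 0.785 TPM (n = 3 each, −4.24, SE 0.04, adjusted p = 1.2e-13). Hbb-bh1 rose from 142.4 ± 2.88 to 5420.3 ± 156.1 TPM (5.24, SE 0.04, adjusted p = 1.57e-14) and Hbb-y from 23.0 to 255.0 ± 3.66 TPM (3.44). Further large rises were Alpk3 (3.01 to 62.0 TPM, 3.98), histidine decarboxylase (Hdc, 1.1 to 21.6 TPM, 3.43), the thrombin receptor relative F2rl2 (0.276 to 12.2 TPM, 3.38), vimentin (Vim, 17.6 to 157.1 TPM, 3.09) and the GTPase gene Rrad (8.23 to 71.8 TPM, 2.99).

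Of 21 members of the red cell membrane and cytoskeleton list 13 fell and 5 rose (18 when adjusted over the list alone, median −0.98, camera adjusted p = 0.0193, but adjusted p = 0.417 with an estimated correlation). Besides Slc4a1, carbonic anhydrase 2 (Car2, 4257.2 to 1634.9 TPM, −1.38) and Dmtn (−2.49) fell, whereas Car1 rose (64.6 to 395.7 TPM). The call was lost with a filter of 5 TPM (adjusted p = 0.0948). Of 18 heme synthesis genes 14 fell and 3 rose (17 when adjusted over the list alone, median −0.42, adjusted p = 0.0108, but adjusted p = 0.417 with an estimated correlation): Alad fell from 514.0 to 64.2 TPM (−2.98) and the mitochondrial iron importer Slc25a37 by 1.55, and Alas2 rose slightly (0.22). Of 9 tested members of the globin list 4 rose and 3 fell (7 when adjusted over the list alone, median 0.32, adjusted p = 0.226). Adult α-globin Hba-a1 fell from 11656.6 ± 1028.3 to 4149.7 ± 93.3 TPM (−1.49) and Hbb-bs went from 21530.5 to 26787.6 TPM (0.32). Stretches of 50 bases shared with other globin copies made up 72.3% of Hba-a1, 53.2% of Hbb-bs and 0% of Hbb-bh1, so levels of single adult copies are uncertain. The summed adult β-globin genes stood at 24421.6 ± 1573.8 TPM in control and 33567.9 ± 3827.2 with both treatments.

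**Figure D3:**
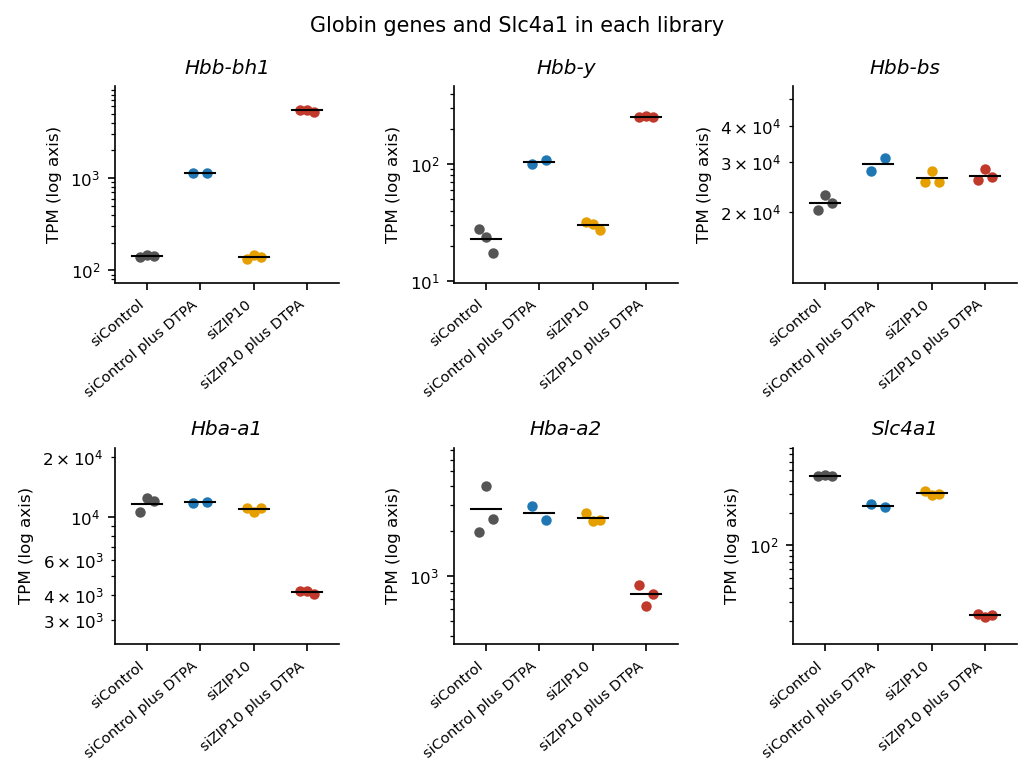
TPM (log axis) of 5 globin genes and Slc4a1 in each library, with a line at the group mean. Hbb-bh1 averaged 142.4, 1138.5 and 5420.3 TPM in siControl, siControl plus DTPA and siZIP10 plus DTPA, while Slc4a1 averaged 445.0, 233.8 and 22.5 TPM.

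Of 18 erythroid regulators 10 fell and 7 rose (18 when adjusted over the list alone, adjusted p = 0.515). Gata1 fell from 2067.0 to 1019.6 TPM (−1.02), the erythropoietin receptor gene Epor from 150.8 to 70.9 TPM (−1.08) and the survival gene Bcl2l1 by 0.70. The Gata1 reads may come from the introduced form, so their fall need not be that of an endogenous gene. Of 13 progenitor genes 8 rose and 2 fell (10 when adjusted over the list alone, median 0.75, adjusted p = 0.00179, but adjusted p = 0.279 with an estimated correlation). Kit rose from 14.5 to 57.3 TPM (1.91), Gata2 from 39.7 to 77.1 TPM (0.94), and the transcription factor genes Spi1 (1.42) and Myb (2.08) rose as well. Of 4 megakaryocyte markers 3 rose (3 when adjusted over the list alone, median 1.51, adjusted p = 0.0203, but adjusted p = 0.149 with an estimated correlation), Itgb3 from 5.96 to 22.4 TPM (1.75), Gp1ba from 7.78 to 27.1 TPM (1.68) and Itga2b by 1.34. Gp9 stood at −0.09 (adjusted p = 0.723). That list was lost with median-of-ratios scaling (adjusted p = 0.0502) and quantile normalization (adjusted p = 0.064). Both tested mast cell genes rose, Hdc and Gata2, as did the lone tested myeloid and lymphoid genes, Cd68 (0.96) and Cd79a (1.17).

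All 21 mitosis genes fell (21 when adjusted over the list alone), with a median of −3.86 (adjusted p = 9.23e-13, and adjusted p = 0.0111 with an estimated correlation), Ccna2 from 205.2 to 10.7 TPM (−4.15) and Mki67 from 174.6 to 10.8 TPM (−3.89). Of 25 DNA replication genes 24 fell and 1 rose (25 called when adjusted over the list alone), with a median of −1.72 (adjusted p = 2.16e-09, and adjusted p = 0.0473 with an estimated correlation), with Mcm6 at −3.47 and Rrm2 at −3.82. All 19 cholesterol genes fell (19 when adjusted over the list alone, median −1.18, adjusted p = 2.16e-09, but adjusted p = 0.149 with an estimated correlation), with Fdft1 going from 279.6 to 98.9 TPM (−1.49). Of 18 NRF2 targets 15 fell and 3 rose (18 when adjusted over the list alone, median −0.67, adjusted p = 0.000421, but adjusted p = 0.147 with an estimated correlation): the glutathione peroxidase Gpx1 fell from 3649.0 to 1190.1 TPM (−1.62), Nqo1 from 75.9 to 13.5 TPM (−2.41) and the peroxiredoxin Prdx2 by 1.08. Of 21 amino acid response genes 14 fell and 3 rose (17 when adjusted over the list alone, median −0.32, adjusted p = 0.0203, but adjusted p = 0.417 with an estimated correlation), with Shmt2 (−1.77) and Mthfd2 (−1.44) as examples. It was lost with a filter of 5 TPM (adjusted p = 0.0816) and quantile normalization (adjusted p = 0.0519). Of 14 heat shock genes 10 fell and 1 rose (11 when adjusted over the list alone, median −0.31, adjusted p = 0.0348, but adjusted p = 0.605 with an estimated correlation), a call lost with a filter of 5 TPM, in each of the other scalings and with voom (adjusted p of up to 0.158).

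Of the p53 targets 7 of 19 rose and 8 fell (15 when adjusted over the list alone, adjusted p = 0.515), with Bbc3 up (0.66) and Ckap2, a spindle gene, down (−1.60). Not called were the metallothionein list (1 of 3 rose and 2 fell, 3 when adjusted over the list alone, adjusted p = 0.508), iron (7 of 16 rose and 6 fell, 13 when adjusted over the list alone, adjusted p = 0.636), autophagy (6 of 18 rose and 8 fell, 14 when adjusted over the list alone, adjusted p = 0.636), glycolysis (7 of 18 rose and 11 fell, 18 when adjusted over the list alone, adjusted p = 0.508) and the unfolded protein response (2 of 17 rose and 11 fell, 13 when adjusted over the list alone, adjusted p = 0.191). The lists of ribosome biogenesis (5 of 24 rose and 12 fell, 17 when adjusted over the list alone, adjusted p = 0.555), interferon (6 of 10 rose and 2 fell, 8 when adjusted over the list alone, adjusted p = 0.208), cell death (6 of 15 rose and 3 fell, 9 when adjusted over the list alone, adjusted p = 0.508), importers (2 of 8 rose and 1 fell, 3 when adjusted over the list alone, adjusted p = 0.523) and exporters (3 of 6 rose and 2 fell, 5 when adjusted over the list alone, adjusted p = 0.636) were not called either. The unfolded protein response was called with no filter (adjusted p = 0.0117). The median, the mean and the test differed in sign for the exporter, iron, p53 and autophagy lists. In all, limma called 7583 of 11379 genes, 3041 higher and 4542 lower, of which 479 and 617 changed at least 2-fold. The share of higher calls was 40.1%, but 49.3% with median-of-ratios scaling, 50.2% after quantile normalization, 49.7% with voom and 47.7% after rescaling to nuclear protein-coding genes. For this comparison Hbb-bs, Alas2, Slc25a37, Dmtn, Car1 and Myb were chosen after their values were seen. The libraries of this group are those with 1.43% to 1.45% mitochondrial rRNA, and 2 of the 10 called lists, mitosis and DNA replication, were kept with an estimated correlation.

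The changes with low zinc and with low ZIP10 were compared across genes. Across 11379 genes the average zinc effect and the average ZIP10 effect of the design correlated with r = 0.71 and rho = 0.69 (covariance 0.101), against r = −0.11 in simulations with no effect. Both averages contain the double-treated group, and its change against control enters both with the same sign. A large change in that group alone therefore raises r, also where the single effects are unlike. The simulations hold no such change, so this r does not measure how alike the single effects are. For the single treatments against the shared control r was 0.55 and rho 0.54, with a covariance of 0.0522 against 0.0128 in the simulations (r = 0.45). Genes are not independent replicates, so no p is given. Low zinc and low ZIP10 shared 600 higher calls, where independence would give 149.1, and 1188 lower calls, where it would give 373. The simulations with no effect gave 0 shared calls, but they make almost no calls in either contrast, so this does not measure the part of the shared control. The opposite directions were taken by 148 genes. The control libraries entered both contrasts, so part of this excess may come from them. Of the 7583 genes called in the double treatment, 1707 (22.5%) were called in the same direction in both single treatments. In that direction, 2320 (30.6%) were called in only 1 of them, and 3556 (46.9%) in neither. The last group can hold genes called the opposite way in a single treatment and single changes that the test missed. It is therefore not a count of genes changed by the double treatment alone.

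The effect of low zinc was also taken within the knockdown. There, Hbb-bh1 rose by 5.28, Car1 by 3.18 and Hbb-y by 3.05, and Slc4a1 fell by 3.70, Nusap1 by 4.09 and Alad by 2.42. All 21 mitosis genes fell (21 when adjusted over the list alone, median −2.47, adjusted p = 1.22e-12, and adjusted p = 0.0114 with an estimated correlation), as did all 19 cholesterol genes (19 when adjusted over the list alone, median −1.14, adjusted p = 1.59e-10, but adjusted p = 0.114 with an estimated correlation). DNA replication genes fell in 22 of 25 cases and rose in 1 (23 when adjusted over the list alone, median −1.09, adjusted p = 3.42e-07, but adjusted p = 0.0645 with an estimated correlation). In heme synthesis 14 of 18 fell and 3 rose (17 when adjusted over the list alone, median −0.39, adjusted p = 0.00426, but adjusted p = 0.348 with an estimated correlation). In the red cell membrane and cytoskeleton list 15 of 21 fell and 5 rose, Car1 among them (20 when adjusted over the list alone, median −0.96, adjusted p = 0.00743, but adjusted p = 0.348 with an estimated correlation). The last call was lost with a filter of 5 TPM (adjusted p = 0.0543). Of the 13 progenitor genes 8 rose and 3 fell (12 when adjusted over the list alone, median 0.63, adjusted p = 0.00342, but adjusted p = 0.279 with an estimated correlation), Spi1 by 1.71 and Kit by 1.76. The megakaryocyte list rose (3 of 4 higher, 4 when adjusted over the list alone, adjusted p = 0.00426, but adjusted p = 0.0835 with an estimated correlation).

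Further falls were in NRF2 targets (16 of 18 lower and 2 higher, 18 when adjusted over the list alone, adjusted p = 6.22e-06, but adjusted p = 0.0645 with an estimated correlation), the amino acid response (15 of 21 lower and 2 higher, 17 when adjusted over the list alone, adjusted p = 0.00356, but adjusted p = 0.279 with an estimated correlation) and heat shock (10 of 14 lower and 1 higher, 11 when adjusted over the list alone, adjusted p = 0.0309, but adjusted p = 0.59 with an estimated correlation). Heat shock was lost with a filter of 5 TPM, in each of the other scalings and with voom (adjusted p of up to 0.135). limma called 6871 genes, 2623 higher and 4248 lower, of which 339 and 382 changed at least 2-fold. The share of higher calls was 38.2%, 48.8% with median-of-ratios scaling, 47.5% after quantile normalization, 49.4% with voom and 49% after rescaling to nuclear protein-coding genes.

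The knockdown was also compared within low zinc. F2rl2 rose by 2.99, the serotonin synthesis gene Tph1 by 2.88, Vim by 2.61 and Hbb-bh1 by 2.25, while Hmmr fell by 4.17, Slc4a1 by 3.32, Alad by 2.28 and Hba-a1 by 1.51. All 21 mitosis genes fell (21 when adjusted over the list alone, median −2.78, adjusted p = 3.49e-16, and adjusted p = 0.00531 with an estimated correlation), as did 24 of 25 DNA replication genes, while 1 rose (25 when adjusted over the list alone, median −1.09, adjusted p = 4.7e-10, and adjusted p = 0.0391 with an estimated correlation). Of 18 heme genes 14 fell and 1 rose (15 when adjusted over the list alone, median −0.41, adjusted p = 1.16e-05, but adjusted p = 0.132 with an estimated correlation), and of 21 red cell membrane genes 13 fell and 5 rose (18 when adjusted over the list alone, median −0.94, adjusted p = 0.00262, but adjusted p = 0.255 with an estimated correlation). Progenitor genes rose in 11 of 13 cases and fell in 1 (12 when adjusted over the list alone, median 0.68, adjusted p = 4.12e-05, but adjusted p = 0.128 with an estimated correlation), with Gata2 (0.95) and Myb (1.73) among them. NRF2 targets (15 of 18 lower and 3 higher, 18 when adjusted over the list alone, adjusted p = 4.54e-05, but adjusted p = 0.0944 with an estimated correlation) and cholesterol genes (18 of 19 lower, 18 when adjusted over the list alone, adjusted p = 2.34e-10, but adjusted p = 0.118 with an estimated correlation) fell. The metallothionein list rose (3 of 3, 3 when adjusted over the list alone, median 0.64, adjusted p = 0.0105, but adjusted p = 0.118 with an estimated correlation). limma called 6037 genes, 2426 higher and 3611 lower, of which 276 and 306 changed at least 2-fold. The share of higher calls was 40.2%, 49% with median-of-ratios scaling, 48.8% after quantile normalization, 49.4% with voom and 52.5% after rescaling to nuclear protein-coding genes.

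The interaction tested whether the DTPA effect differed with the knockdown. Mitosis genes fell further than the sum of the single changes. Slc4a1 had a log2 interaction of −2.77 (adjusted p = 8.62e-10), Nusap1 fell by 2.90 beyond it, Ube2c by 2.84, Alad by 1.71 and Hba-a1 by 1.42. Hbb-bh1 (2.29), F2rl2 (2.82), Car1 (2.69) and Gata2 (1.21) rose beyond it. The mitosis median was −1.08 and −1.32 in the single treatments, sums of the single changes had a median of −2.40, and the double treatment reached −3.86 (interaction median −1.45, 21 of 21 lower, 21 when adjusted over the list alone, adjusted p = 6.02e-15, and adjusted p = 0.00681 with an estimated correlation). For heme synthesis the sum was −0.21 and the double treatment −0.42 (12 of 18 lower and 2 higher, 15 when adjusted over the list alone, adjusted p = 8.24e-07, but adjusted p = 0.106 with an estimated correlation). Red cell membrane genes had −0.23 and −0.98 (13 of 21 lower and 5 higher, 18 when adjusted over the list alone, adjusted p = 0.000331, but adjusted p = 0.147 with an estimated correlation). Cholesterol synthesis had −0.41 and −1.18 (18 of 19 lower, 18 when adjusted over the list alone, adjusted p = 4.11e-13, but adjusted p = 0.0877 with an estimated correlation). NRF2 targets had −0.22 and −0.67 (16 of 18 lower and 1 higher, 18 when adjusted over the list alone, adjusted p = 1.99e-07, and adjusted p = 0.0435 with an estimated correlation).

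For p53 targets the interaction ran against the direction of the single changes. Their sum was 0.41 and the double treatment 0 (15 of 19 lower and 1 higher for the interaction, 16 when adjusted over the list alone, adjusted p = 1.05e-05, but adjusted p = 0.0853 with an estimated correlation), with Ccng1 at −0.56 and Trp53inp1 at −0.65. Progenitor genes had a sum of 0.29 and reached 0.75 (7 of 13 higher, 8 when adjusted over the list alone, adjusted p = 0.000148, but adjusted p = 0.113 with an estimated correlation), including Kit (1.28) and Spi1 (1.16). Of DNA replication genes 14 of 25 were lower and 2 higher (16 when adjusted over the list alone, median −0.44, adjusted p = 0.000546, but adjusted p = 0.113 with an estimated correlation). Megakaryocyte markers were higher in 3 of 4 cases (3 when adjusted over the list alone, median 0.74, adjusted p = 0.0133, but adjusted p = 0.106 with an estimated correlation). limma called 3687 genes for the interaction, 1369 higher and 2318 lower, of which 190 and 136 had an interaction of at least 2-fold. Of the 3313 that were also called in the double treatment, 3133 had an interaction in the direction of the double change and 180 against it. The share of higher calls was 37.1%, 46% with median-of-ratios scaling, 44.2% after quantile normalization, 46.3% with voom and 55.2% after rescaling to nuclear protein-coding genes.

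**Figure D4:**
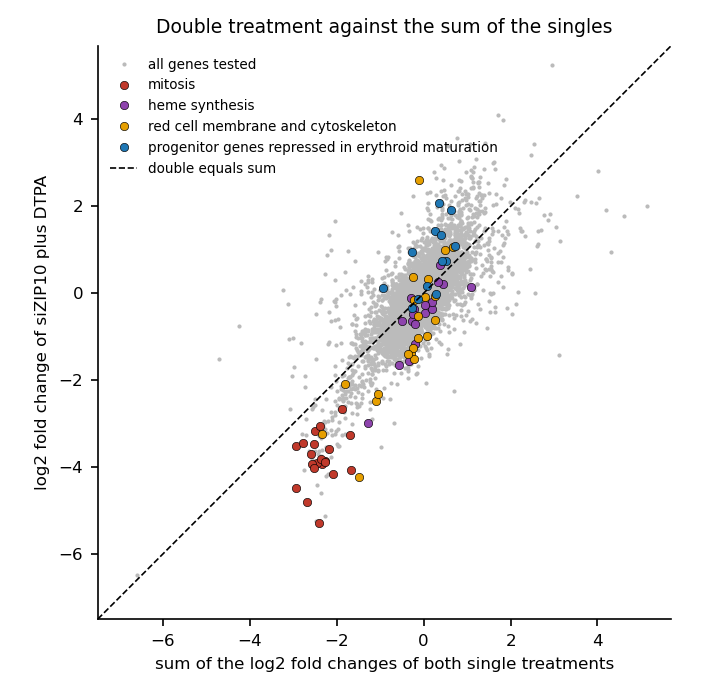
Log2 change under both treatments (vertical) against the sum of the log2 changes under low zinc and low ZIP10 (horizontal) for each tested gene, with mitosis, heme, red cell membrane and progenitor genes in colour and a dashed line where both are equal. The mitosis genes, with a median sum of −2.40 and a median double change of −3.86, lie under the line.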

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

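Tests chosen only after the results were seen are the rescaling to nuclear protein-coding genes, the comparison of depth, the comparison of Hbb-bh1 with summed adult β-globin, and voom.

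The DTPA effect differed between knockdown and control cells, by the interaction test of limma, for 3687 genes. Among the zinc genes the log2 interaction was −0.70 for Slc39a10, 0.41 for Mt1 and 0.95 for Slc30a1. That of Slc39a10 was not called with a pseudocount of 0.1 (−0.1, adjusted p = 0.81) or with voom (0.05, adjusted p = 0.891), and its TPM rose 8.05-fold with DTPA in control cells and 8.14-fold in knockdown cells. The largest positive ones were Snord93 (3.69), Snord35a (3.33), Mir6979 (3.18), F2rl2 (2.82) and Car1 (2.69), and the largest negative ones Mir7048 (−4.54), Snord42b (−3.12), Nusap1 (−2.90), Ube2c (−2.84) and Hmmr (−2.77). The short noncoding genes lie within host genes and are hard to count in such libraries, so their values are uncertain. Each of Snord35a, Mir6979 and Snord42b lost its call with no filter (adjusted p = 0.069, 0.0613 and 0.0749), and Mir6979 with voom (2.92, adjusted p = 0.0842). Mir6979 also lost it without siControl plus DTPA replicate 1 (adjusted p = 0.0648) or replicate 2 (0.0646), siZIP10 replicate 1 (0.0501) or replicate 3 (0.0506), or siZIP10 plus DTPA replicate 1 or replicate 2 (0.0508 each), with an interaction of 2.82 to 3.8 over the libraries left out. Snord35a also lost it without siControl replicate 1 (adjusted p = 0.0528) or replicate 3 (0.0504), or siControl plus DTPA replicate 2 (2.67, adjusted p = 0.111). Snord42b also lost it without siControl replicate 1 (adjusted p = 0.0572) or replicate 3 (0.0587), siControl plus DTPA replicate 1 (−2.65, adjusted p = 0.11), siZIP10 replicate 2 (0.0569) or replicate 3 (0.0559), or siZIP10 plus DTPA replicate 1 (0.0592) or replicate 3 (0.0571).

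Of the gene lists, 15 differed. The median interaction was 0.41 for the metallothionein list, −0.38 for heme synthesis (Alad −1.71), −0.87 for red cell membrane (Slc4a1 −2.77), 0.37 for progenitor genes (Gata2 1.21), −1.45 for mitosis, −0.44 for DNA replication (Mcm6 −1.48), −0.37 for p53 targets (Ccng1 −0.56) and −0.16 for the amino acid response (Mthfd2 −0.99). It was 0.11 for the unfolded protein response (Canx −0.36), −0.39 for NRF2 targets (Prdx2 −0.97), −0.21 for autophagy (Bnip3l −0.59), −0.22 for glycolysis (Pfkp −1.25), 0.21 for ribosome biogenesis (Nolc1 0.36), −0.68 for cholesterol synthesis (Fdft1 −1.21) and 0.74 for megakaryocyte markers (Gp1ba 1.27). Canx went against the direction of its list. With an estimated correlation mitosis and NRF2 targets were kept, and the other 13 were not: the metallothionein, progenitor and DNA replication lists had an adjusted p = 0.113 each, heme and megakaryocyte 0.106, red cell membrane 0.147, p53 0.0853, cholesterol 0.0877, autophagy 0.224, the amino acid response and ribosome biogenesis 0.273, the unfolded protein response 0.442 and glycolysis 0.612. Glycolysis was also lost with a filter of 5 TPM and in each of the other scalings (adjusted p of up to 0.148), and the unfolded protein response without the trend (0.0545).

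The first pattern is the fall of the mitosis genes in doubly treated cells beyond the sum of the single changes (median interaction −1.45). The double-treated libraries hold more mitochondrial rRNA and less nuclear coding RNA, and after each library was rescaled to its nuclear protein-coding genes the median was −1.52. After the trends on GC content and exon length had been removed from each library it was −1.42, with 21 of 21 members still called lower, while the interaction calls among 11149 genes went from 3620 to 4128. The double libraries were not shallower, with 103.3% of the mean recovered reads of the others. These values argue against make-up, GC or length bias and depth as its whole cause. An effect of both treatments on dividing cells may remain as a hypothesis, and a change in the number of living cells was not measured here.

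The second pattern is the rise of Slc30a1 in doubly treated cells (1.54) while Mt1 and Mt2, targets of the same zinc sensor, fell. After rescaling to nuclear protein-coding genes the rise was 1.63 (SE 0.04). The 1 annotated gene that overlaps Slc30a1 exons held 2.04% of the recovered reads that Slc30a1 gained (134 reads, against a rise of Slc30a1 from 3000 to 9557). The rescaling applies 1 factor to all genes of a library, and nuclear protein-coding shares ranged only from 77.33% to 84.08%. A uniform shift of that size is too small to give this rise. The rescaling could not have brought it near 0, so other effects of make-up remain untested. The reads counted for the overlapping gene cannot exclude that gene. Any of its reads placed on Slc30a1 would not be among them, and the strand setting is unknown. Control of Slc30a1 by something other than the zinc that sets metallothionein levels is a candidate explanation, which was not tested.

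The third pattern is the rise of Hbb-bh1 in doubly treated cells (5.24). Of its 564 stretches of 50 bases, 0% occur in another globin transcript, and Hbb-bh1 changed by 4.78 more (log2) than the summed adult β-globin genes. These values argue against reads shared with other copies and against a constant share of adult β-globin reads placed on Hbb-bh1. A less mature state of these cells may be an explanation. The design has a single time point and no library without estradiol, so it cannot show this. It also cannot show whether Hbb-bh1 was kept on or newly raised. Other transcripts went both ways. The progenitor list had a median change of 0.75, while summed adult β-globin stood at 33567.9 ± 3827.2 TPM against 24421.6 ± 1573.8 in control.

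The 6 libraries of a comparison of 3 against 3 can be split in 10 ways, and the real split gave the most calls in 1 of 10 each time. Low ZIP10 called 3480 genes, and the highest other split 0; the double treatment called 7583 and the highest other split 1; DTPA within the knockdown called 6871 and the highest other split 0. With 10 splits no share under 0.05 can be reached.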

How the results depend on the processing

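Alternatives chosen only after the data were seen were the fit with the duplicated library as labelled, voom on the recovered reads and the rescaling to nuclear protein-coding genes. The number of calls in each of the 6 comparisons stayed within 1.5 times its main value in each alternative run, leaving out single libraries included. Over the 11 libraries left out in turn, calls ranged from 2206 (without siControl plus DTPA replicate 2) to 3270 for low zinc, 2805 to 3423 for low ZIP10, 7157 to 7599 for the double treatment, 6372 to 6846 for DTPA within the knockdown, 4932 to 6052 for the knockdown within DTPA and 2992 to 3517 for the interaction. Over the same libraries the log2 change of Slc39a10 ranged from 2.55 to 2.67, −1.25 to −1.11, 0.69 to 0.79, 1.86 to 2, −1.91 to −1.8 and −0.75 to −0.61, and the correlation of the average effects from 0.64 to 0.72. A lone siControl plus DTPA library was then assumed to vary like the other groups. With a replicate block there were 3137, 3470, 7582, 6853, 5940 and 3641 calls. With the duplicated library as labelled, Slc39a10 stood at 1.33, −1.16, 0.75, 1.91 and −0.58 with its calls lost, its interaction reversed to 0.58, Mt1 and Mt2 for the knockdown within DTPA reversed to −0.5 and −2, the Mt1 interaction to −0.73, and the correlation was 0.85; here a knockdown library with normal zinc stands in the DTPA group. Slc39a10 changed by −1.93 (low ZIP10) and 2.87 (DTPA within the knockdown) with a pseudocount of 0.1 and by −2.05 and 3.1 with voom, against −1.16 and 1.91. The interaction of Slc39a10 was −0.1 with a pseudocount of 0.1 and 0.05 (reversed) with voom. The correlation was 0.59 with a pseudocount of 0.1 and 0.81 after rescaling, and the interaction of Ftl1 reversed to 0.05 under quantile normalization. For these the cause was not tested. For named genes, leaving out libraries kept direction and side of the threshold in 6416 cases, lost 102 calls and added 2, where genes uncalled both times count as kept. For lists, an estimated correlation lost 52 calls over 138 tests, fry added 42 and the fit with no filter added 12. Only the groups compared gives no interaction or correlation, and the fit without trend was not used for the correlation. Depth limits Slc39a10 in siZIP10, with 21 to 36 reads a library.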

Other observations

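The gene families and genes in this part were chosen after their values were seen, as was the rescaling to nuclear protein-coding genes.

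No set test was run on the families described here. Called members were counted, and 66.6% of the 11379 genes were called with the double treatment, so the counts alone do not set a family apart from other genes. Of 84 tested cytosolic ribosomal protein genes, 67 rose with low zinc (median 0.21, 0.19 to 0.25 over the scalings) and 73 rose and 5 fell with both treatments (median 0.40, 0.40 to 0.50), but with low ZIP10 alone 7 rose and 12 fell (median −0.01). Of 35 proteasome subunit genes 28 fell with low zinc (median −0.18), 29 fell and 1 rose with low ZIP10 (−0.16), and 34 fell and 1 rose with both (−0.52, −0.52 to −0.37 over the scalings). Nuclear genes of complex I subunits and assembly factors fell in 40 of 51 cases with both treatments (median −0.51, −0.51 to −0.40) and those of ATP synthase in 17 of 21 cases (−0.64, −0.64 to −0.46), and of 80 mitochondrial ribosomal protein genes 64 fell and 1 rose (−0.41, −0.41 to −0.31). Of 13 mitochondrially encoded protein genes 3 rose with both treatments (median 0.17, 0.08 to 0.26 over the scalings, with between 0 and 6 members higher and between 0 and 2 lower). The mitochondrial rRNAs rose, mt-Rnr1 from 1635.6 to 7928.6 TPM (2.28) and mt-Rnr2 from 1057.2 to 6464.5 TPM (2.61), and so did the small nuclear RNA Rn7sk (26.9 to 133 TPM, 2.31). A change in the polyadenylation or capture of such RNAs was not measured here.

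Single genes picked for their size of change rose with both treatments, with no list or enrichment test behind them. Laptm5, a lysosomal protein of blood cells, averaged 113.9, 234.4, 134.4 and 681.7 TPM in siControl, siControl plus DTPA, siZIP10 and siZIP10 plus DTPA (log2 change with both 2.57). The signalling gene Vav1 went from 29.7 to 195.7 TPM (2.68), the granule proteoglycan gene Srgn from 41.1 to 245.6 TPM (2.55), the integrin gene Itgb2 from 21.5 to 94.3 TPM (2.08), Prex1 from 16 to 116.9 TPM (2.80), Fyb from 18.5 to 125.3 TPM (2.70) and the cytokine receptor gene Il2rg from 2.71 to 17.9 TPM (2.35). The serotonin synthesis gene Tph1 went from 1.8 to 18.3 TPM (2.79), Ddc from 0.922 to 12.2 TPM (2.78) and Hdc from 1.1 to 21.6 TPM (3.43). These directions were kept under each of the other scalings.

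Among the 148 genes called in opposite directions by the single treatments was Creb3l3, which fell with low zinc (−1.14), rose with low ZIP10 (0.46) and fell further with both (−2.98, 23.4 to 2.13 TPM). Rragd, a regulator of nutrient signalling, did likewise (−0.71, 0.36 and −1.68). Hba-x rose with low zinc (1.19), fell with low ZIP10 (−0.87) and stood at 0.23 with both (adjusted p = 0.161), which passed after rescaling to nuclear protein-coding genes (0.32, adjusted p = 0.0294). Mylk3 rose with low zinc (1.01), fell with low ZIP10 (−0.20) and rose with both.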
